A study of Homo sapiens with 12 samples.

How the data were processed

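Total RNA of SH-SY5Y cells was measured on single-colour Illumina bead arrays, with biotin-labelled material prepared from 12 samples and 1 array per sample. The arrays fall into 3 groups of 4 per the labels: a control siRNA and 2 siRNAs against SETD1A, s18789 and s18790, all harvested 96 hours after transfection. Nothing in the sources used here says that the 4 samples of a group were separate cultures, so p-values measure the spread between these samples, which can be technical. No pair of arrays held identical values.

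The deposited table holds the mean bead intensity of each probe on a linear scale, without background subtraction or normalization between arrays, as its values show, and was made with GenomeStudio per the submitters' processing notes. Beside each intensity the authors deposited a detection p-value, the share of negative control bead types at least as bright, per the file headers and the steps of the values. A second deposited table holds log2 values of the same arrays, which keep the order of each array's intensities and share a common distribution across arrays (median 6.33 on every array). The transform that made those log2 values is not given in the sources used here, and they served only as an alternative source of values. The chip or slide of each array was not given in the sources used here, so no such batch was analysed here.

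The array holds 47321 probes. A probe table paired 30113 of them with 1 gene symbol and 8 with several, and 17200 were unnamed here. Of the symbols, 30074 could be checked through the gene identifier against a current table of human genes and 0 changed. No gene coordinates are given, since the deposited values name no genome build; gene spans from the GRCh38.p14 annotation served only to test for trends with gene length.

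Background was corrected and arrays were normalized with limma 3.58.1 in R 4.3.3, by the normal-exponential model fitted through the detection p-values, an offset of 16, quantile normalization and log2. A probe was kept where its detection p was under 0.01 on at least 4 of the 12 arrays, which left 15922 probes, 12654 of them with a symbol, for 9833 genes, and 3268 unnamed. All 12 arrays entered a single linear model with a mean per group, which gives 9 residual degrees of freedom, and contrasts were tested with moderated statistics (lmFit, contrasts.fit and eBayes). A probe is termed called where its Benjamini-Hochberg adjusted p over all kept probes was under 0.05. Errors of log2 fold changes are standard errors (SE) of this model. Where a gene had several probes, the probe with the highest mean log2 intensity stood for it. The number of arrays limits the precision.

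A gene above background on no array of a group has only a bound there. In that case the fold is given as at least the ratio of the brighter group's mean to the dimmer group's mean of, per array, the higher of the probe's own level and the lowest level among probes above background, with the fitted adjusted p.

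The level of SETD1A was also compared with an exact two-sided permutation test over the 70 arrangements of 4 against 4 arrays, whose smallest possible p is 0.0286. The genes named in the text followed a rule set before the data were examined, as were the 27 gene lists, the test of each comparison and most alternatives, while several tests of explanations were chosen only after results were seen. The rule took SETD1A; for each siRNA, up to 12 genes with the largest rise and 12 with the largest fall among called genes whose 4 values all lay on one side of the 4 control values; the genes called for both siRNAs in the same direction, up to 12 each way; up to 6 genes each way between the siRNAs; and up to 4 members per list with the largest mean change over both siRNAs. Genes named outside this rule are said to be chosen after their values were seen.

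Gene lists were tested with limma's camera against all other genes, with a preset correlation between genes of 0.01, and adjusted over the 25 lists with at least 5 measured genes. The test was repeated with the correlation estimated for each list. Members past the test were counted over all probes and also adjusted over the list alone.

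Because both siRNAs were compared with the same controls, overlaps and correlations were set beside 100 simulations of unchanged groups sharing controls, beside the overlap of independent lists, and beside all 6 ways of giving the siRNAs separate pairs of control arrays. The count for each comparison was set beside all 35 splits of its 8 arrays, and the count shared by both siRNAs beside 100 groupings of the 12 arrays, the real one included.

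The procedure was tested on simulated data for the comparison of s18790 with control, with 15922 probes and independent normal noise per probe. It recovered 22% of 50 probes changed by 0.5 on the log2 scale, 82% of 50 changed by 1, 96% of 50 changed by 1.5 and 90% of 50 changed by 2, with 6 false calls.

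Alternatives were no background correction, median scaling in place of quantile normalization, the deposited log2 values, no detection filter, detection on all 12 arrays, 1 probe per gene, the replicate number as a block, each array left out in turn, array weights, a fit of only the groups compared, and trended robust moderation. A pair of further alternatives was chosen after the data were seen: leaving out both outlying arrays, and the main axis of variation within groups as a covariate.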

Results

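SETD1A encodes a methyltransferase that places methyl groups on lysine 4 of histone H3, and rare damaging variants in it are associated with schizophrenia. To ask which transcripts change when its level is lowered, SH-SY5Y cells, a human neuroblastoma line with features of sympathetic neurons, received a control siRNA or either of 2 siRNAs against SETD1A, s18789 and s18790. Expression was measured 96 hours after transfection on 12 bead arrays, 4 per group. The median intensity of an array lay between 63.1 and 70.2, and 29.1% to 33.6% of its probes were detected. Correlations between arrays ranged from 0.896 to 0.994.

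The first principal component held 60.6% of the variance and separated s18790 replicate 2 (83.7) and control replicate 4 (26.8) from the other arrays of their groups. On the second component s18790 replicates 1, 3 and 4 lay lowest, between -26.1 and -20.6, while s18789 replicate 1 (10.4) lay within the range of the controls and s18790 replicate 2 (0.96) within that of s18789. The lowest detected shares were those of s18790 replicate 2 (29.1%) and control replicate 4 (29.3%). Genes of the Fanconi and homologous recombination list, which repair DNA crosslinks and breaks, lay below the other arrays of the group on both, with median log2 deviations of -0.80 on s18790 replicate 2 and -0.28 on control replicate 4. Histone genes lay above, at 0.52 and 0.20, as did synaptic vesicle genes, at 0.44 and 0.24.

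**Figure D1:**
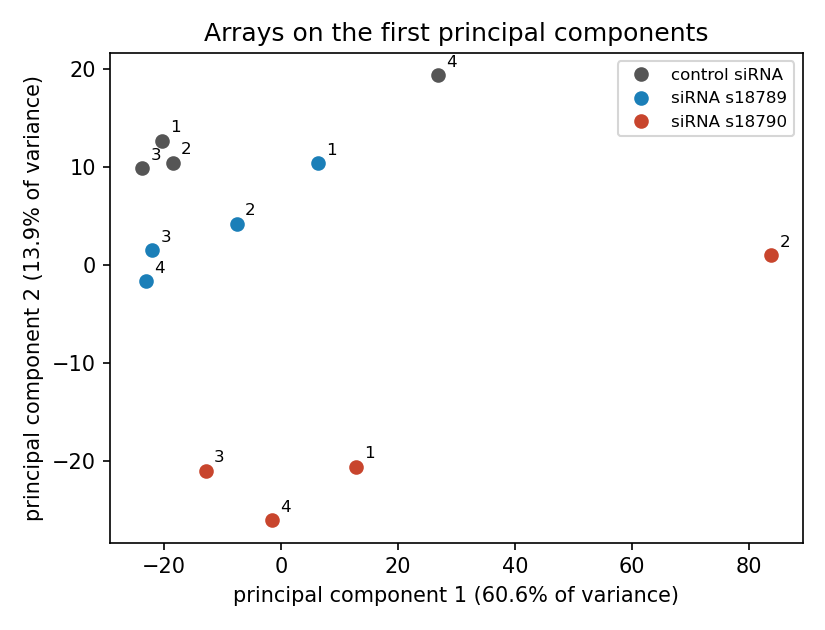
Position of each array on the first and second principal components of the normalized log2 intensities (both in component units), coloured by group and numbered by replicate. s18790 replicate 2 lies at 83.7 and control replicate 4 at 26.8 on the first component, apart from the other arrays of their groups.

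SETD1A was lower on all 4 arrays of each siRNA than on any control array. Its probe (ILMN_1714327, the only SETD1A probe measured) had a log2 intensity of 7.67 ± 0.25 (SD, n = 4) in controls, 7.24 ± 0.11 (SD, n = 4) with s18789 and 7.04 ± 0.28 (SD, n = 4) with s18790. With s18790 the level was 64.6% of control (log2 difference -0.63, 95% interval -0.96 to -0.30, limma adjusted p = 0.0276). With s18789 it was 74.1% of control (log2 difference -0.43, interval -0.77 to -0.10), and the adjusted p over all probes was 0.616. The exact permutation test gave p = 0.0286 for each siRNA, the smallest value 4 against 4 arrays can give. The siRNAs themselves differed by -0.20 (interval -0.53 to 0.14, adjusted p = 0.468; exact permutation p = 0.229). In control and s18790 groups the highest SETD1A value came from the array that lay apart, at 8.03 on control replicate 4 and 7.45 on s18790 replicate 2. The s18790 call was lost without control replicate 1, control replicate 2, s18790 replicate 1 or s18790 replicate 4, with adjusted p of 0.0507, 0.0683, 0.0730 and 0.0660. It was also lost without the detection filter (0.0502) or with only the groups compared in the fit (0.0999).

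**Figure D2:**
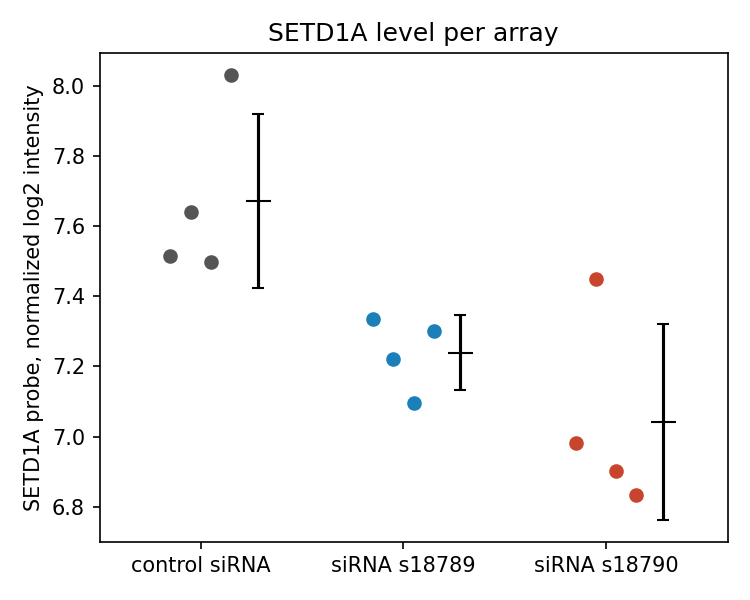
Normalized log2 intensity of the SETD1A probe on each array (points), with the mean and SD of each group of 4 (bars). All values with either siRNA lie below the lowest control value of 7.50.

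With s18789, 7 genes rose and 3 fell. ADGRG2, an adhesion G protein-coupled receptor, rose 2.25-fold (log2 1.17 ± 0.09 SE, n = 4 against 4, adjusted p = 0.000168). DCX, a microtubule-binding protein of migrating neurons, rose by 0.96 ± 0.15 (adjusted p = 0.0393), and GAP43, a growth cone protein, by 0.84 ± 0.13 (0.0393). The neuropeptide gene NTS was below background on every control array and at least 1.31-fold higher (adjusted p = 0.0185), and the small Cajal body RNA SCARNA8 was at least 1.19-fold higher (0.0211). CHST15, a sulfotransferase acting on chondroitin sulfate, fell by 1.29 ± 0.13 on the log2 scale (adjusted p = 0.00167). CXCR4, the receptor of the chemokine CXCL12, fell by 0.74 ± 0.12 (0.0393), and CORIN, a membrane protease that processes natriuretic peptides, fell below background on all 4 arrays, at least 1.45-fold lower (0.0393). The remaining genes that rose were CGNL1, a cell junction protein, by 1.04, and TMEM100, a membrane protein, by 0.84.

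In all, 15 of 15922 probes were called, 9 higher and 6 lower, 4 of them unnamed. At an unadjusted p under 0.05 there were 958 probes, where 796.1 would be expected with no effect, and the groups did not overlap for 7.08% of probes against 2.86% by chance. The count was 80 without s18790 replicate 2, whose spread enters the shared error, and lay between 3 and 11 with any other array left out. CHST15 and ADGRG2 kept their calls in each of the 24 alternatives run, while the other 8 genes lost theirs with 1 or more arrays left out.

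Of 25 gene lists tested with s18789, 4 were called, none of which kept its call with an estimated correlation. Genes of G1/S and DNA replication were shifted upward, with 34 of 36 members positive, a median of 0.11 and camera adjusted p = 2.34e-05 (adjusted p = 0.227 with an estimated correlation). No single member passed limma's test over all probes or adjusted over the list alone, and 5 had an unadjusted p under 0.05; GINS2 and GINS3, parts of the replicative helicase, had values of 0.37 and 0.35. The G2/M and mitosis list also shifted upward (median 0.11, 34 of 43 positive, adjusted p = 0.00956; adjusted p = 0.255 with an estimated correlation), again with 0 members past the test and 0 at an unadjusted p under 0.05; FOXM1, a mitotic transcription factor, was at 0.33. Its call was lost with array weights (0.0665), without both outlying arrays (0.167) and without control replicate 4 alone (0.166), an array on which these genes lay at a median of -0.07 from the other controls. The ATF4 and amino acid stress list shifted upward (median 0.10, 18 of 24 positive, adjusted p = 0.00858; adjusted p = 0.606 with an estimated correlation), with 0 members past the test, 1 at an unadjusted p under 0.05, and SLC7A5, an amino acid transporter, at 0.28; without s18789 replicate 1 its adjusted p was 0.0870. Mesenchymal neuroblastoma markers shifted downward (median -0.20, 4 of 18 positive, adjusted p = 0.000351; adjusted p = 0.484 with an estimated correlation). Of these markers 0 passed over all probes, 2 had an unadjusted p under 0.05 and 1 was lower adjusted over the list alone; the repressor SNAI2 stood at -0.54 and the collagen COL3A1 at -0.28.

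With s18790, MAGEC2 and MAGEC1, melanoma-associated antigens of the testis, were at least 2.8-fold (adjusted p = 5.2e-05) and 1.64-fold higher (0.00328), and GTSF1, a germ cell factor in small RNA silencing, at least 1.57-fold higher (0.000311); each was below background on every control array. STMN4, a neuronal stathmin, rose 3.95-fold (log2 1.98 ± 0.17 SE, n = 4 against 4, adjusted p = 7.46e-05), CBLN2, a secreted synapse organizer, 2.56-fold (1.36, 6.38e-05), and MYCN, a transcription factor amplified in many neuroblastomas, 2.55-fold (1.35, 0.000262). The metallothionein MT1F rose 2.64-fold (0.000296). HS6ST2, a heparan sulfate sulfotransferase, fell to 0.351 of control (log2 -1.51 ± 0.22, adjusted p = 0.0017), and INTS2, a subunit of the Integrator complex that processes small nuclear RNAs, to 0.370 (-1.44, 0.0237).

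Further genes that rose were the membrane proteins ADGRG2 (1.34) and TMEFF2 (at least 2.12-fold), the adaptor SH2D3C (1.39), TTC9B (at least 1.78-fold) and TACC2, a centrosomal coiled-coil protein (at least 1.6-fold). Among those that fell, BBS10, a chaperonin-like protein of cilia, was at least 1.79-fold lower, the artemin co-receptor GFRA3 at least 1.5-fold lower and CORIN at least 1.31-fold lower. LRRC17 fell by 1.32, FAM200C by 1.33, the complement component C5 by 1.29, the centromere protein ITGB3BP by 1.28, the centriole protein CETN3 by 1.27, the chloride channel protein CLIC4 by 1.23 and OSGEPL1, a transfer RNA modifying enzyme of mitochondria, by 1.23. FAM200C was above background on 1 of 4 s18790 arrays, INTS2, LRRC17 and C5 on 3 of 4, STMN4 on 3 of 4 control arrays and SH2D3C on 2 of 4. INTS2 was lowest on s18790 replicate 2, at 5.70 against 7.22 to 7.43 on the other s18790 arrays. The same held for LRRC17 (4.77 against 6.15 to 6.59) and C5 (5.40 against 6.83 to 7.16). HS6ST2, FAM200C, ITGB3BP, CETN3 and CLIC4 were also lowest on that array, which enlarged the mean falls of all these genes. The INTS2, LRRC17 and C5 calls were lost without control replicate 1 (adjusted p = 0.0704, 0.0587 and 0.108), 2 (0.0714, 0.0590 and 0.106) or 3 (0.0788, 0.0636 and 0.116), and that of C5 without s18790 replicate 1 (0.0697) or s18789 replicate 2, 3 or 4 (0.0552 to 0.0575). Without the detection filter the 3 calls were lost as well (0.0654, 0.0563 and 0.101), as with only the groups compared in the fit (0.0890, 0.0828 and 0.119).

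For s18790, 1325 of 15922 probes were called, 642 higher and 683 lower, 164 of them unnamed and 113 changed more than 2-fold. They stood for 1055 genes, 540 higher and 516 lower; BOLA2, chosen after its values were seen, had a probe in each direction. With median scaling the split was 173 higher and 636 lower of 809, and that scaling moved the median of all probes to -0.08 with s18790, 0.08 with s18789 and -0.14 between the siRNAs. The count fell to 583, 609 and 612 without control replicates 1, 2 and 3, to 714 without s18790 replicate 1 and to 430 with only the groups compared in the fit.

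**Figure D3:**
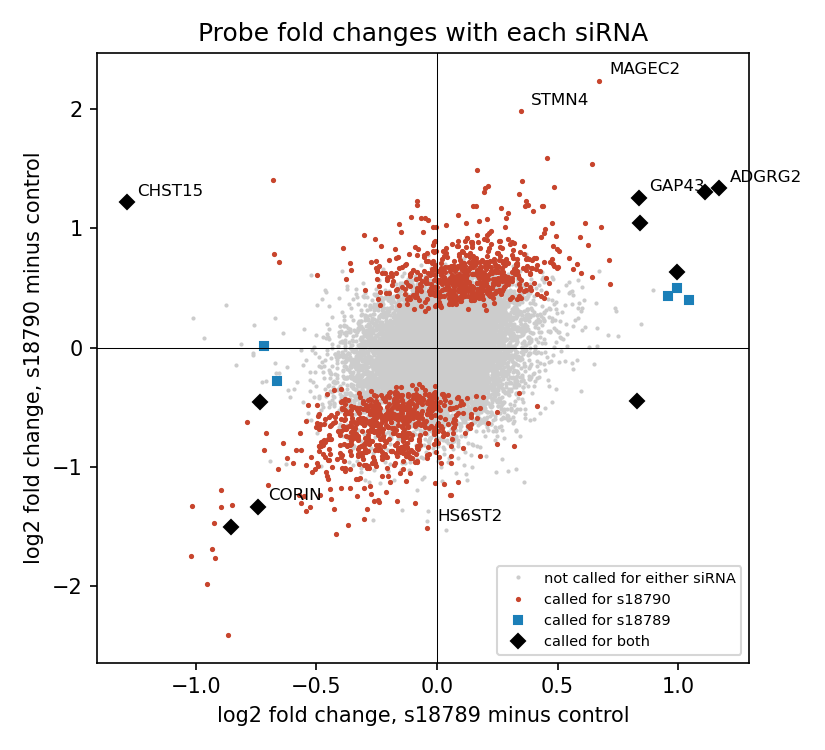
Log2 fold change of each probe against control with s18789 (horizontal axis) and s18790 (vertical axis), coloured by which siRNA it was called for. CHST15 lies at -1.29 and 1.22, while ADGRG2 lies at 1.17 and 1.34.

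Of the 25 lists, 7 were called with s18790, and each had adjusted p = 0.767 with an estimated correlation. Replication-dependent histone genes were called upward: 6 of 10 members rose and 4 did not pass the test, 8 were higher adjusted over the list alone, and the median was 0.65 (camera adjusted p = 8.08e-05). H2BC12 rose by 1.07 ± 0.12, H2BC5 by 0.89 ± 0.10 and H1-2, a linker histone, by 0.71; the other 3, chosen after their values were seen, were H2BC21 (0.74), H2AC18 (0.69) and H2AC6 (0.62). The H1-2, H2BC21 and H2AC18 calls were lost without control replicate 1, 2 or 3 (adjusted p from 0.0514 to 0.0825). That of H2BC21 was also lost without s18790 replicate 1 (0.0633), and that of H2AC6 without control replicate 2 (0.0576). On s18790 replicate 2 these genes lay a median of 0.52 above the other s18790 arrays. Synaptic vesicle and exocytosis genes shifted upward (median 0.28, 21 of 23 positive, adjusted p = 0.0031), and on s18790 replicate 2 they lay a median of 0.44 above the other s18790 arrays. SLC18A3, the vesicular acetylcholine transporter, rose by 1.19 and BSN, an active zone scaffold chosen after its values were seen, by 0.44; 21 members did not pass, and 11 were higher adjusted over the list alone. Autophagy and lysosome genes shifted upward (median 0.22, adjusted p = 0.0202): 4 of 33 rose, the proton pump subunit ATP6V0D1 by 0.72, the autophagosome protein WIPI2 by 0.65 and, chosen after their values were seen, CTSA by 0.53 and ULK1 by 0.37, and adjusted over the list alone 8 were higher and 2 lower. These genes lay a median of 0.20 above the other s18790 arrays on s18790 replicate 2 and 0.13 above the other controls on control replicate 4. The BSN, ATP6V0D1, CTSA and ULK1 calls were lost without control replicate 1, 2 or 3 (adjusted p from 0.0561 to 0.103). Those of BSN, CTSA and ULK1 were also lost without s18790 replicate 1 (0.0777, 0.0610 and 0.0764), those of CTSA and ULK1 without s18790 replicate 4 (0.0515 and 0.0504), and that of BSN without s18789 replicate 2 or 4 (0.0503 and 0.0504). With median scaling the calls of H1-2, H2BC21, H2AC18, H2AC6, BSN and all 4 autophagy genes were lost (0.0648 to 0.255, with 0.0897 for WIPI2 and 0.0912 for ATP6V0D1), and with only the groups compared these and SLC18A3 (0.0505 to 0.119). That of H2BC21 was lost without the detection filter (0.0512).

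Of 20 immediate early and MAPK response genes, the AP-1 subunit JUN rose by 1.04 and the feedback inhibitor SPRY4 by 0.74, 5 were higher adjusted over the list alone, and the list was called upward (median 0.13, adjusted p = 0.0246). Its genes lay a median of 0.28 above the other arrays of the group on s18790 replicate 2 and 0.14 on control replicate 4. Adrenergic neuroblastoma markers were called upward (median 0.11, adjusted p = 0.0457), with 6 of 20 higher, the same number adjusted over the list alone, and 13 not past the test. HAND1 (1.05), MYCN (1.35) and DLK1 (0.83), regulators of sympathoadrenal cells, and GAP43 (1.26) rose, whereas CHGB, a secretory granule protein chosen after its values were seen, fell by 0.69. Mesenchymal markers were called downward (median -0.13, adjusted p = 0.0236): YAP1, a Hippo pathway coactivator, fell by 1.12 (above background on 1 of 4 s18790 arrays), COL3A1 by 0.86 and SNAI2 by 0.48, while the collagen COL1A1 rose by 0.64 and 14 of 18 did not pass, with the same counts adjusted over the list alone. On s18790 replicate 2 and control replicate 4 these markers lay 0.36 and 0.15 above the other arrays of their groups. Mitochondrial ribosome genes were called downward (median -0.03, mean -0.13, adjusted p = 0.0226), with 12 lower, 2 higher and 59 not past the test, and 13 lower and 2 higher adjusted over the list alone. MRPS25 fell by 1.17 and MRPS33 by 0.88, and on s18790 replicate 2 the list lay 0.33 above the other arrays of its group. The mitochondrial ribosome, adrenergic and mesenchymal calls were each lost without control replicate 4 (adjusted p = 0.106, 0.0874 and 0.0874) and without s18790 replicate 3 (0.0825, 0.108 and 0.113), the first and second also without s18790 replicate 1 (both 0.134), and the mesenchymal call without s18790 replicate 4 (0.0611). The immediate early call was lost without s18790 replicate 1 (0.105) or s18790 replicate 2 (0.0533), and the adrenergic call without s18789 replicate 1 (0.0519). Among the genes, the SPRY4 call was lost without control replicate 2 or 3 or s18790 replicate 1 (0.0583, 0.0566 and 0.0556), COL1A1 without control replicate 1 (0.0528) and SNAI2 without control replicate 3 (0.0603). With median scaling the mesenchymal list (0.0850) and SPRY4 (0.0562) lost their calls. The adrenergic, mesenchymal and immediate early calls were lost with probes detected on all 12 arrays (each 0.0772). The mitochondrial ribosome, adrenergic and mesenchymal calls were lost with the within-group axis as a covariate (0.0879, 0.0660 and 0.0879). Those of the adrenergic list, SNAI2 and COL1A1 were lost with only the groups compared (0.0508, 0.0803 and 0.0632).

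**Figure D4:**
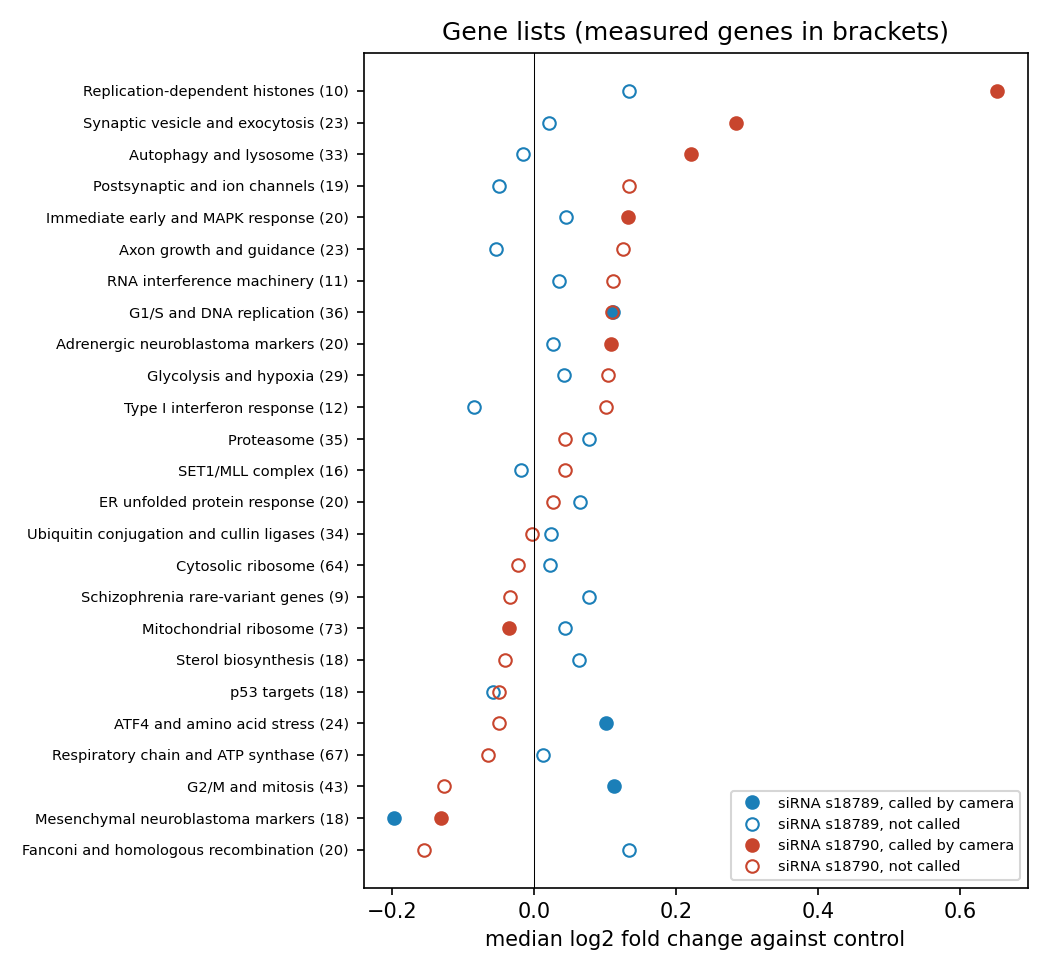
Median log2 fold change of each tested gene list against control with s18789 and s18790; filled points were called by camera with the preset correlation, open points were not. The histone list lies at 0.65 with s18790 and 0.13 with s18789.

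Lists close to SETD1A itself were not called with either siRNA. In the SET1/MLL complex list of 16 measured genes, SETD1A and DPY30, a shared core subunit, fell with s18790 (-0.63 and -0.41, adjusted p = 0.0305 for DPY30), and the list's adjusted p was 0.857 with s18790 and 0.429 with s18789. Adjusted over that list alone, 2 members were higher and 2 lower with s18790. The list of genes with rare variants in schizophrenia held 9 measured genes, of which SETD1A, the siRNA target, alone passed the test with s18790. The camera adjusted p of this list was 0.725 with s18790 and 0.429 with s18789. Adjusted over the list alone, 1 member was lower with s18789, and 1 was higher and 1 lower with s18790. Between the siRNAs 1 member was called higher with s18790. Type I interferon genes, which can respond to transfected RNA, had adjusted p of 0.132 with s18789 and 0.826 with s18790, where the regulator IRF7 rose by 0.67 (adjusted p = 0.0305). Within the RNA interference machinery, AGO1 rose by 0.60 with s18790 (adjusted p = 0.0101), and the list's adjusted p was 0.573. The DPY30 and IRF7 calls were lost without control replicate 1 (adjusted p = 0.0841 and 0.0852), 2 (0.102 and 0.0876) or 3 (0.0818 and 0.0989), without s18790 replicate 1 (0.0895 and 0.0837) and with only the groups compared in the fit (0.115 and 0.0976). With median scaling the DPY30, IRF7 and AGO1 calls were lost (0.0869, 0.0918 and 0.0652), and without the detection filter that of IRF7 (0.0619). Adjusted p of the lists not called ranged from 0.0720 to 0.999 with s18789 and from 0.0975 to 0.938 with s18790. List median and mean differed in sign for axon growth and the schizophrenia genes with s18789, for the unfolded protein response and sterol biosynthesis with s18790, and for G1/S and mesenchymal genes between the siRNAs, none of them called in that comparison.

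To ask which changes both siRNAs gave, the comparisons were intersected. ADGRG2 (1.17 and 1.34), GAP43 (0.84 and 1.26), TMEM100 (0.84 and 1.05) and NTS (at least 1.31-fold and at least 1.02-fold) rose with both, and CXCR4 (-0.74 and -0.45) and CORIN (at least 1.45-fold and 1.31-fold lower) fell with both. CORIN was below background on every array of either siRNA. Its bounds reflect the background level of those arrays, so the smaller bound with s18790 does not mean a smaller fall. ADGRG2 was called by both of its probes with each siRNA. The s18790 call of CXCR4 was lost without any 1 of the 4 controls (adjusted p from 0.0519 to 0.101) or without s18790 replicate 1 or 4 (0.0928 and 0.0699), and that of NTS without control replicate 2 (0.0528). Both were lost with median scaling (0.0750 and 0.0612) and with only the groups compared in the fit (0.104 and 0.0619). CHST15 changed in opposite directions, falling by 1.29 with s18789 and rising 2.33-fold with s18790. The other probe with opposite fitted signs was unnamed and below background on every control and s18790 array, so no direction is given for it with s18790.

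Of 10 probes called for both siRNAs, 8 changed in the same direction, 5 higher and 3 lower, against 0.363 and 0.257 for independent lists. Unchanged groups sharing controls gave a median of 0 in 100 simulations (mean 40.7). In 1 of these the count reached 8 or more, at 4070 probes, so a far larger shared count can arise without an effect. With the controls split between the siRNAs, 0 probes were called for both by limma, since the s18790 comparison then called 0. In those splits 210 to 349 probes had an unadjusted p under 0.05 for both in the same direction. Across probes the fold changes correlated at r = 0.349 (Spearman rho = 0.303), where probes are not independent replicates, the median of the simulations was 0.556, and the split controls gave -0.209 to 0.43. The covariance was 0.0205, below the 0.0211 expected from the residual variance of shared controls and above the 0.0156 expected from the variance of the controls alone. With split controls it lay between -0.0200 and 0.0263 (mean 0.00485), and 38 of 100 simulations gave as large a value, so a shared effect over all probes was not resolved. Among the 1325 probes called for s18790, 1101 (83.1%) had the same sign with s18789, where as many probes with the lowest p in the simulations gave a median of 90.2%, and 66 of 100 simulations gave as large a share. Over all probes the share was 60.3% against a simulated median of 68.9%. The count of 8 was 43 without s18790 replicate 2 and lay between 2 and 7 with any other array left out.

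Set directly against s18789, s18790 gave higher levels of CHST15 (2.51 ± 0.13, adjusted p = 1.19e-06), MT1F (2.08 ± 0.15, 5.99e-05), STMN4 (1.64, 0.000675) and MAGEC2 (1.57, 0.000863). TLE2, a transcriptional corepressor, and GFRA2, the neurturin co-receptor, were higher by 1.46 and 1.37, with fold changes of opposite sign against control (-0.67 and 0.79 for TLE2, -0.65 and 0.72 for GFRA2), of which those with s18790 passed the test. Among genes lower with s18790 were HS6ST2 (-1.47, adjusted p = 0.00381), CLIC4 (-1.29, 0.00238), the neuropeptide VIP (-1.28, 0.0379), CPED1 (-1.21, 0.0372), TMEM64 (-1.17, 0.00242) and PIP4P2, a lysosomal lipid phosphatase (-1.13, 0.0245). The VIP and CPED1 calls were lost without control replicate 1, 2 or 3 (adjusted p from 0.0535 to 0.0578), s18789 replicate 2, 3 or 4 (0.0837 to 0.122) or s18790 replicate 1 (0.0885 and 0.0798). That of VIP was also lost without s18789 replicate 1 (0.0772) and that of CPED1 without s18790 replicate 4 (0.0663). The PIP4P2 call was lost without any 1 of the s18789 arrays (0.0612 to 0.0765) or s18790 replicate 1 (0.0522), and without the detection filter the VIP, CPED1 and PIP4P2 calls were lost too (0.0915, 0.0883 and 0.0582), as with only the groups compared (0.0910, 0.102 and 0.0628).

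Between the siRNAs 668 probes were called, 373 higher and 295 lower with s18790, for 310 genes higher and 230 lower. With median scaling, 102 were higher and 591 lower of 693. The lists called higher with s18790 were histones (median 0.48, adjusted p = 0.000933), synaptic vesicle (0.26, 0.0023), autophagy and lysosome (0.27, 0.0023) and adrenergic genes (0.18, 0.0337), each with adjusted p = 0.443 with an estimated correlation. H2BC12 (1.11) and H2BC5 (0.78) were higher, the other 8 histones did not pass, and 6 were higher adjusted over the list alone. G2/M genes were called lower (median -0.22, adjusted p = 0.000933; adjusted p = 0.136 with an estimated correlation), with 6 of 43 positive. Of the list, CKS1B alone, a kinase subunit chosen after its values were seen, passed the test (-0.42), a call lost without any 1 array except control replicate 4, s18790 replicate 2 and s18790 replicate 4 (adjusted p from 0.0555 to 0.123), with median scaling (0.0594) and with only the groups compared (0.114). G2/M genes lay a median of 0.15 lower on s18790 replicate 2 than on the other s18790 arrays; HMMR stood at -1.56 (adjusted p = 0.113), with 5.37 on that array against 7.06 to 7.98 on the others of its group. Mitochondrial ribosome genes (median -0.14, adjusted p = 0.000933; adjusted p = 0.66 with an estimated correlation) and respiratory chain genes (-0.10, 0.0337; adjusted p = 0.693 with an estimated correlation) were called lower, among them MRPS33 (-0.74) and NDUFB5 (-0.41). The NDUFB5 call was lost without any 1 array except control replicate 4 and s18790 replicates 2 and 3 (0.0529 to 0.0912) and with only the groups compared (0.113). The count of 668 fell to between 205 and 323 with any s18789 array left out, to 257 without s18790 replicate 1, to 429 and 443 without control replicates 2 and 1, and to 200 with only the groups compared in the fit; it was 1082 without s18790 replicate 3. The respiratory chain and adrenergic calls were lost without s18789 replicate 1 (0.0704 and 0.0701), s18790 replicate 1 (0.258 and 0.0998) or s18790 replicate 3 (0.146 and 0.113). The respiratory chain call was also lost with median scaling (0.125) and with the within-group axis as a covariate (0.245), and the adrenergic call with probes detected on all 12 arrays (0.0550).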

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

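The tests of array intensity and of gene length on the outlying arrays, the comparison of s18790 replicate 2 with control replicate 4, the 3 tests of a scaled-down response and the count without s18790 replicate 2 were chosen only after the results were seen.

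s18790 replicate 2 and control replicate 4 lay apart from their groups, and the gap of control replicate 4 stood out on the first component (gap of 0.896 of the group's range, 26.8 against -23.7 to -18.5) and in its mean correlation with its own group (0.872, 0.971 against 0.985 to 0.987). A lower mean intensity is argued against, since 9 of the other 11 arrays had a lower one than s18790 replicate 2 and 8 had a lower one than control replicate 4. By other measures s18790 replicate 2 lay low, with a median of 64.9 (63.1 to 70.2 over all arrays) and a 90th percentile of 412.1 (316.7 to 471.1). Control replicate 4 stood at 70.2 and 440.1. A lower intensity shared by both arrays is thus argued against, while one on s18790 replicate 2 alone stays open. A trend with gene length could account for part of the gap: across 9828 genes, gene span and the deviation from the other arrays of the group had Spearman rho of -0.341 on s18790 replicate 2 and -0.293 on control replicate 4, against -0.242 to 0.306 on the other arrays. Whether s18790 replicate 2 is a mislabelled control was left open by the planned test, in which 74.9% of 2571 probes lay nearer to the other s18790 arrays against a bound of 75%, and was argued against by the 30.4 percentage points by which it exceeded control replicate 4 (44.5%). The source of the length trend stays open, and no biological explanation was tested because the labels give these arrays no difference from their groups.

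The siRNAs differed, with 668 probes called between them although SETD1A itself did not pass that test. The same response scaled down by a weaker knockdown with s18789 is argued against for CHST15, whose change reversed and differed by 2.51 on the log2 scale. Of the other 13 probes called with s18789, 2 had larger changes with s18789. An unnamed one stood at -0.72 against 0.02, a difference of 0.73. CGNL1 stood at 1.04 against 0.40, a difference of -0.64. That difference did not pass the test without any 1 of the s18789 arrays or without s18790 replicate 1 or 4 (adjusted p from 0.0648 to 0.0947). Both probes were selected by their change on the same s18789 arrays, which favours a larger change there, so no conclusion is drawn from them. For the remaining probes a scaled response stays possible and could not be decided: with separate pairs of control arrays, from 57.7% to 80.7% of the probes with the lowest p for s18790 had the same sign with s18789, and the lowest shares came from the 3 splits that set control replicate 4 with s18789. Opposite calls covered 1 named gene in the main fit and most alternatives. They covered 4 without s18790 replicate 2, 3 without both outlying arrays, 8 with array weights and 36 with the axis covariate. In those fits reversal was not confined to CHST15. MT1F, TLE2 and GFRA2, selected by their difference between the siRNAs, lay below every control with s18789 and above every control with s18790. Their falls with s18789 were not called. That s18790 replicate 2 makes the difference is argued against, since 952 probes were called without it. Effects of either siRNA on transcripts other than SETD1A stay open as a biological explanation and were not tested, as the siRNA sequences were not used here.

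The replication-dependent histone list was called upward with s18790 at a median of 0.65 with the preset correlation (adjusted p = 0.767 with an estimated correlation), with 6 of 10 members past the test, and lay 0.52 above the other s18790 arrays on s18790 replicate 2. That this array carries the change is argued against by a median of 0.535 without it. Their short spans, a median of 526 bases against 28458 for other genes, could produce such a shift through the length trend, yet the median was 0.637 after the trend of fold change on gene span was subtracted. A higher level of these transcripts with s18790 remains as a hypothesis, and polyadenylation or cell cycle phase, which the arrays do not measure, were not tested.

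Among 135 groups of 4 arrays examined, 15 had an array with a gap above Dixon's critical value, where chance gives about 1 in 20, or 6.75. Control replicate 4 was the array in GAP43 (gap 0.839, 8.01 against 7.50 to 7.58) and MT1F (0.878, 7.71 against 7.21 to 7.28), on which it was highest. The gaps computed for this array in MAGEC2 (0.832) and MAGEC1 (0.905) are between levels below background on every control array, so no order is given for them. It was lowest for BBS10 (0.916, 6.03 against 6.68 to 6.74), CETN3 (0.835, 8.41 against 8.90 to 8.99), VIP (0.934, 8.57 against 9.31 to 9.37) and PIP4P2 (0.833, 6.97 against 7.58 to 7.70). INTS2 was lowest on s18790 replicate 2 (0.88, 5.70 against 7.22 to 7.43) and CHST15 on s18790 replicate 3 (0.84, 8.41 against 8.80 to 8.88). With s18789, C5 was lowest on replicate 1 (0.905, 7.29 against 7.74 to 7.79) and GAP43 on replicate 3 (0.86, 8.39 against 8.50 to 8.52), and SH2D3C was lowest on control replicate 3 (0.832, 5.25 against 5.72 to 5.81).

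Beside CHST15, the genes that the rule took for the largest differences past limma's test between the siRNAs were MT1F (2.08), STMN4 (1.64), MAGEC2 (1.57), TLE2 (1.46) and GFRA2 (1.37), higher with s18790. Those it took as lower were HS6ST2 (-1.47), CLIC4 (-1.29), VIP (-1.28), CPED1 (-1.21), TMEM64 (-1.17) and PIP4P2 (-1.13).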

How the results depend on the processing

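Leaving out both outlying arrays and the within-group axis as a covariate were chosen after the data were seen. None of the named genes or lists called reversed its direction in any alternative, and calls of named genes were kept in 1857 instances and lost in 347, those of lists kept in 380 and lost in 52; uncalled genes passed the test in 192 instances and uncalled lists in 48. No background correction, the deposited log2 values, 1 probe per gene and trended robust moderation left the SETD1A calls and the counts of probes and lists within 1.5 times. Except with an estimated correlation, the lists called in each alternative were G1/S and mesenchymal genes with s18789, histones, synaptic vesicle and autophagy genes with s18790, and G2/M, histones, mitochondrial ribosome, synaptic vesicle and autophagy genes between the siRNAs. Dim genes are limited by signal over background, as on each array 29.1% to 33.6% of probes were detected. A block for chip was not run because the chip was not given, and camera was not run with trended robust moderation, which it does not use. The cause was not tested for the changes below, except that a fit of fewer arrays has fewer degrees of freedom.

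With median scaling, 809 probes were called with s18790, 4 for both siRNAs in the same direction, and 10 lists with s18789. Without the detection filter SETD1A with s18790 stood at -0.63 with limma adjusted p = 0.0502. Keeping probes detected on all 12 arrays gave 9 probes with s18789, 5 for both and 4 lists with s18790. Array weights gave 385, 3117 and 1577 probes with s18789, with s18790 and between the siRNAs, and 227 for both. A fit of only the groups compared gave SETD1A with s18790 at -0.63 (adjusted p = 0.0999) and 41, 430 and 200 probes. Without both outlying arrays SETD1A differed between the siRNAs by -0.33 (adjusted p = 0.0407; range over the alternatives 0.0407 to 0.69), and 124, 2795 and 1644 probes were called, 68 for both. With the axis as a covariate SETD1A with s18789 stood at -0.43 (adjusted p = 0.0118; range 0.0118 to 1) and 497, 6007 and 5656 probes were called, 297 for both. Of 49 regroupings of the arrays in the same fit, 20, 0 and 0 called as many (medians 60, 17 and 85, highest 6126, 4932 and 5503), so the count with s18789 is not a measure of that siRNA. The axis was taken from the residuals of these same arrays, which lowers the error by construction. No conclusion is therefore drawn from the adjusted p of SETD1A in that fit. With an estimated correlation camera called 0 lists with s18789, 0 with s18790 and 0 between the siRNAs, and at an unadjusted p under 0.05 there were 2, 0 and 2.

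Whether the replicate number pairs the arrays was not resolved. Of 12 pairs of same-numbered arrays 6 had a correlation of deviations over 0.1 (range -0.583 to 0.575). Only 3 of 12 arrays correlated best with their own number. Replicate 3 was positive between all groups (0.371, 0.575 and 0.463), while the other numbers had both signs. The main axis of variation within groups held 70.2% of that variance and enters these correlations, so they cannot exclude pairing. With the replicate block, SETD1A with s18790 was at -0.63 (adjusted p = 0.0510; range over the alternatives 6.67e-05 to 0.0999), 3, 834 and 296 probes were called, 2 for both.

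With each array left out in turn, SETD1A ranged from -0.49 to -0.31 with s18789, from -0.77 to -0.51 with s18790 and from -0.33 to -0.13 between the siRNAs. Called probes ranged from 3 to 80 with s18789, from 583 to 1793 with s18790 and from 205 to 1082 between the siRNAs, and from 2 to 43 for both. Lists called ranged from 3 to 6, from 4 to 7 and from 5 to 10. The correlation of fold changes ranged from 0.20 (without s18789 replicate 1) to 0.61 (without control replicate 4), with a jackknife SE of 0.366.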

Other observations

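The tests of small nucleolar and Cajal body RNAs were chosen only after the result was seen, as were the counts at an unadjusted p in other splits. The cancer-testis and metallothionein families were chosen after MAGEC1, MAGEC2, GTSF1 and MT1F had been seen to change. Those genes were left out of the family tests, which use the same arrays. Their camera p-values therefore do not come from lists fixed beforehand.

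PLXNA1, a receptor of semaphorins, which steer growing axons, was higher with s18790 than with s18789 by 0.79 (limma adjusted p = 0.00186), PLXNA4 by 0.60 (0.0372) and PLXNA2 by 0.51 (0.0341). Another plexin of the axon list, PLXNB1, stood at 0.37 (0.216), and the cytoskeletal protein DPYSL3 was lower by -0.42 (0.0421). Against control, s18790 gave 0.62 for PLXNA1 (limma adjusted p = 0.00318) and 0.44 for PLXNA4 (0.0825). It gave only 0.13 for PLXNA2 (0.523) and -0.12 for DPYSL3 (0.49). The differences between the siRNAs thus include changes with s18789 and are not changes with s18790 alone. Among synaptic membrane proteins, the NMDA receptor subunit GRIN1 differed by 0.71 (0.0135) and the adhesion protein NLGN2 by 0.52 (0.0231), and NRXN2 rose by 0.61 with s18790 against control (0.0363). Except for PLXNA1, each of these calls was lost with 1 or more arrays left out. This held for PLXNA4, PLXNA2 and DPYSL3 without control replicate 1 or 2 or s18789 replicate 2, 3 or 4 (adjusted p from 0.0503 to 0.112), DPYSL3 also without control replicate 3 (0.0659), and NLGN2, PLXNA4 and DPYSL3 without s18789 replicate 1 (0.0599, 0.0763 and 0.0980). GRIN1 and NLGN2 lost theirs without s18789 replicate 3 or 4 (0.0528 to 0.0839), NLGN2 without s18789 replicate 2 (0.0561), NLGN2, PLXNA2 and PLXNA4 without s18790 replicate 1 (0.0685, 0.0871 and 0.0917), and PLXNA2 and DPYSL3 without s18790 replicate 4 (0.0687 and 0.0860). NRXN2 lost its call without any 1 array except control replicate 4, s18789 replicate 3 and s18790 replicates 2 and 3 (0.0510 to 0.115). With median scaling the calls of these genes other than PLXNA1 were lost (0.0529 to 0.194), and with only the groups compared in the fit those other than PLXNA1 and GRIN1 (0.0501 to 0.123). Without the detection filter PLXNA4 and NRXN2 lost theirs (0.0589 and 0.0692). Neither list was called between the siRNAs, with camera adjusted p of 0.388 for axon growth and guidance and 0.0553 for postsynaptic genes.

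Respiratory chain genes moved in both directions with s18790: 6 of 67 fell, among them NDUFB5 of complex I (-0.65 ± 0.09 SE, adjusted p = 0.0016), SDHC of complex II (-0.56, 0.0164) and the ATP synthase subunit ATP5PO (-0.55, 0.00302), 1 rose (NDUFA10, 0.53, 0.0465) and 60 did not pass, and the list was not called with s18790 (adjusted p = 0.103). In the p53 target list XPC, which recognises DNA damage, fell by 0.53 with s18790 (0.00387) and SPATA18 by 0.70 (0.0453), the cell cycle inhibitor CDKN1A was higher by 0.60 between the siRNAs (0.0245), and the list's adjusted p was 0.736 with s18790. Within G1/S genes TK1 (0.58), GINS2 (0.48) and GINS3 (0.42) rose with s18790 whereas 2 members fell, among them RFC5 by 0.58. Adjusted over the list alone 6 were higher and 3 lower, and the list's adjusted p was 0.27. The TK1, GINS2 and GINS3 calls were lost without control replicate 1, 2 or 3 (adjusted p from 0.0606 to 0.0937), that of SDHC without control replicate 1 (0.0553), and that of NDUFA10 without any 1 array except control replicate 4 (0.0539 to 0.144). SPATA18, above background on 2 of 4 s18790 arrays, lost its call without any 1 array except control replicate 4 and s18790 replicates 1 and 3 (0.0511 to 0.136), and CDKN1A without s18789 replicate 2, 3 or 4 or s18790 replicate 1 (0.0597 to 0.0867). With median scaling ATP5PO (0.0517), NDUFA10, CDKN1A, TK1, GINS2 and GINS3 lost theirs (0.127 to 0.228). With only the groups compared NDUFA10, SDHC, SPATA18, CDKN1A, TK1, GINS2 and GINS3 did (0.0518 to 0.124), and without the detection filter NDUFA10 and SPATA18 (0.0828 and 0.0994). Too few members of the other 2 lists were measured for a test: 3 of 8 H3K4 demethylase genes, with KDM5B at 0.07, KDM2B at 0.22 and KDM1A at 0.10 with s18790, and 1 of 15 Schwann and glial markers, SOX9, at 0.08. Genes in these paragraphs that the rule for named genes did not take were chosen after their values were seen.

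A hypothesis was that the rise of MAGEC1, MAGEC2 and GTSF1 with s18790 may extend to the other cancer-testis genes. Of 7 others measured 6 were positive, MAGEA10 (1.09) and MAGEA2 (0.58) rose, and the median was 0.322 (camera adjusted p = 0.00872 over 3 families; adjusted p = 0.132 with an estimated correlation), or 0.185 without s18790 replicate 2. The MAGEA2 call was lost without control replicate 1, 3 or 4, s18789 replicate 4 or s18790 replicate 1 or 4 (0.0517 to 0.101). It was also lost with no background correction, median scaling, the deposited log2 values, no detection filter, array weights, only the groups compared or both outlying arrays left out (0.0520 to 0.101). Members of this family have similar sequences, so their probes are not fully separate measurements.

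Another hypothesis was that the difference of MT1F between the siRNAs may be shared by metallothioneins, small proteins that bind metal ions. MT2A (0.86), MT1X (0.93) and MT1E (0.69) were all higher with s18790 than with s18789 (camera adjusted p = 6.6e-05; adjusted p = 0.0393 with an estimated correlation). The MT1E call was lost without control replicate 2 or 3, any 1 of the s18789 arrays or s18790 replicate 4 (0.0509 to 0.111), with median scaling (0.0721), without the detection filter (0.0696) and with only the groups compared (0.0935). These genes are also close in sequence.

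The rise of SCARNA8 with s18789 may also extend to other small nucleolar and Cajal body RNAs. Of 60 others 38 were positive at a median of 0.0725 (camera adjusted p = 0.00872; adjusted p = 0.117 with an estimated correlation), and 0 passed limma's test over all probes, with 5 at an unadjusted p under 0.05.

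Other splits of the arrays were set beside the real groups to ask whether chance could give the counts. In fits of the 8 arrays compared, 1 of 35 splits, the real one, called as many probes in each comparison: 41 with s18789, 430 with s18790 and 200 between the siRNAs, against a highest other count of 0 by limma. For both siRNAs in the same direction 1 of 100 groupings of the 12 arrays, the real one, called as many, with 8 probes against a highest other of 0. In these adjusted counts the real groups ranked first, and 1 of 35 is the lowest share such splits can give. Every other split mixes the groups compared, which adds any difference between them to the error. A count of 0 there therefore does not by itself exclude chance. In addition, 1 of 100 simulations of unchanged groups sharing controls gave 8 or more for both siRNAs, at 4070 probes. There, unlike in the real groups, outlying deviations could move into the shared controls from another group. Nor can chance splits be excluded at an unadjusted p under 0.05. There the real groups gave 1604, 3049, 2872 and 491 probes and the highest other 2500, 4654, 2958 and 2052. The highest other count with s18790 came from the split that set control replicate 4 with s18790 replicates 1, 2 and 4, and that with s18789 from the split that set it with s18789 replicates 1, 2 and 3, a structure of the arrays that the groups do not explain.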
